A study of Phyllostachys edulis with 12 samples.

How the data were processed

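The data are RNA-seq counts per gene from whole moso bamboo seedlings. Per the labels, total RNA was extracted with an RNeasy kit, and libraries were made with a NEBNext Ultra RNA kit for Illumina sequencing. The labels do not say whether the strand was kept. Per the submitters' processing notes, HISAT2, a spliced read aligner, was used. Its version, the genome build, the annotation and the tool that counted reads are not given in the sources used here. The deposited table holds 1 whole-number count per gene and library, read as raw counts because the values are whole and each column has its own total, and it holds a gene length from 138 to 396795 (median 2897), which was used only in checks. The treatment of reads that fit several genes is not given in the sources used here, so genes with near-identical copies or overlapping genes on the opposite strand are uncertain.

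The labels describe 12 samples in 4 groups of 3. Columns of the table were matched to samples by the code in each sample's description. This gave 11 count columns, with 3 libraries each for the control, 0.5 h and 1 h and 2 for 24 h. One further column of counts (1 column) matched no sample's labels and was not used in any step, and 1 labelled sample, 24 h replicate 3, was not analysed here. The match rests on these codes, and the table's codes run without the gap that the labels' codes have. If the table was numbered apart from the labels, the unused column may also be a 24 h library, the libraries called 24 h replicates 1 and 2 would be replicates 2 and 3, and the pairing check, the block and the 24 h group size would change. The design had been written for 3 libraries at 24 h, and the tests were run as written with 2. The labels do not say whether replicates are separate plants or pools, nor give a harvest day, clock time or library batch. The p-values therefore measure only the spread between these samples, which may be technical, and a batch that follows the groups cannot be told apart from the treatment.

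Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr, which left 39640 of 47091 genes. Counts were scaled with TMM factors. All 11 libraries entered 1 quasi-likelihood fit with a mean per group, so that the 4 groups share 1 estimate of the spread, with 7 residual degrees of freedom and 3.86 prior degrees of freedom. Each contrast was tested with edgeR's quasi-likelihood F-test, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested in that contrast. Genes with an adjusted p under 0.05 were called, with no limit on the fold change. Standard errors are the log2 fold change divided by the square root of its F statistic. The contrasts were 0.5 h, 1 h and 24 h against the control, 1 h against 0.5 h, 24 h against 1 h, and a joint test of any cold time against the control. CPM values are counts scaled to a common total with the TMM-scaled library size. Log2 CPM for principal components and correlations used a prior count of 2. These choices were made before the data were examined.

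Gene lists for cold response, hormones, photosynthesis, cell wall and other functions had been written in advance as name and description patterns. The table does not pair identifiers with names, so none could be tested. The rule for named genes then allowed 4 identifiers: the gene with the largest rise and the gene with the largest fall at 1 h and at 24 h, among those with an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between the cold and the control libraries. At 24 h that last condition compared 2 libraries with 3. No gene was called lower at 1 h, so the rule gave 3 identifiers, and PH01221966G0010 was added after its values were seen.

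The scripts were tested on simulated data. In counts drawn from fitted means and dispersions for 38913 genes, with 67 genes changed 2-fold, 67 changed 4-fold and 66 changed 8-fold between 0.5 h and control, the test recovered 46.3% of the 2-fold, 91.0% of the 4-fold and 98.5% of the 8-fold changes, with 7 false calls among 164. In the real 0.5 h and control counts, with as many of the 39640 genes thinned by these factors, it recovered 49.3%, 83.6% and 93.9%, and 51 of the 202 calls were among the other genes. For 24 h against control, drawn counts of 38853 genes gave 35.8%, 86.6% and 97.0%. Thinned real counts of 39607 genes gave 71.6%, 92.5% and 97.0%, with 3091 of the 3268 calls among the other genes. These thinned counts keep the real response at 24 h, so a thinned gene may already have changed. Those shares are thus not the recovery of known folds alone. The changed genes put into the data loosen the adjusted threshold, as does the real response in the thinned 24 h counts. The shares thus do not describe a comparison with as few calls as at 0.5 h and 1 h, where the threshold is stricter. Total counts for replicates 1 to 3 were 32253264, 33609845 and 30331928 in the controls, 29304206, 33873890 and 32369595 at 0.5 h and 34543663, 32652226 and 31344042 at 1 h, and for replicates 1 and 2 they were 29953291 and 32510246 at 24 h.

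Alternatives tried were other scalings (RLE, upper quartile, library size only), DESeq2, no filter and a stricter filter (at least 1 CPM in 3 libraries and a mean of 20 counts), a fit of only the groups compared, the replicate number as a block, an adjusted p under 0.01, a 2-fold limit, and each library left out in turn. A robust estimate of the spread, the removal of a length trend per library, and a fit without 207 genes that 1 library alone held at least 8-fold apart from the rest were added after the data were seen, as was a fit of 24 h against control with every library thinned at random to 29304206 counts, the smallest total. Overlaps between times were set against 20 simulations in which every group had the same mean.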

Results

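Gene expression was measured by RNA sequencing in seedlings of moso bamboo (Phyllostachys edulis), a large woody grass, at 3 weeks of age. Seedlings at the 3-leaf stage were kept in a freezing chamber at -2 °C for 0.5 h, 1 h or 24 h, under the same light and day length as the untreated control seedlings. The comparisons ask how the seedling transcriptome differs from the control after each time in the cold, and how it differs between consecutive times. The count table covered 3 control libraries, 3 libraries at 0.5 h, 3 at 1 h and 2 at 24 h. Total counts per library lay between 29304206 and 34543663, and between 40595 and 41705 genes had at least 1 count in a library. Of 47091 genes in the table, 39640 were counted highly enough to be tested, 27288 with an identifier of the PH01 type and 12352 listed as newGene. The table does not pair its identifiers with gene names or descriptions, so genes are given by identifier alone, and no cold-response pathway or gene family was tested.

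The 24 h libraries stood apart from the rest of the libraries. On the first principal component of log2 CPM (counts scaled to a common library size), which held 22.9% of the variance, the 24 h libraries lay at 131 and 127, and the other 9 libraries lay between -42.2 and -11.8. The second component held 11% and placed the 24 h libraries among the others. Across genes, the Pearson correlation of log2 CPM between a 24 h library and a library of another group was 0.916 to 0.929, and that between the pair of 24 h libraries was 0.946. Libraries of different groups among control, 0.5 h and 1 h correlated at 0.935 to 0.952, a range that covers the 0.944 to 0.952 found within those groups. The 10 most abundant genes took 7.33% and 6.89% of the counts at 24 h and 4.66% to 6.60% in the other libraries. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom was 17.2.

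**Figure D1:**
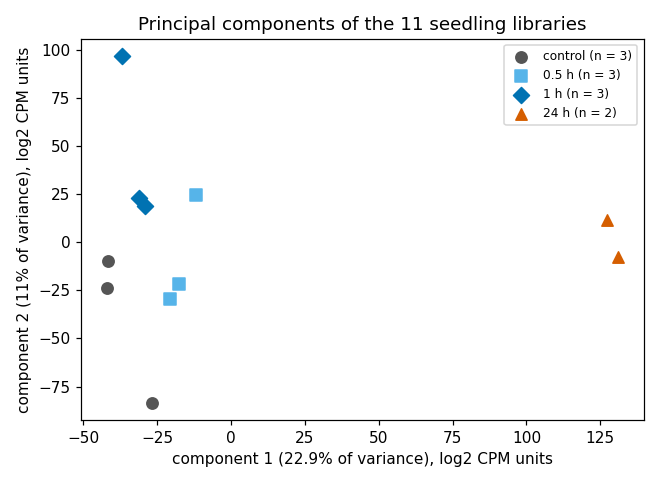
Each point is 1 library, placed by its first component (horizontal axis, 22.9% of the variance) and second component (vertical axis, 11%) of log2 CPM over 39640 genes, with the colour and marker giving the group. The 24 h libraries sit at 131 and 127 on the first component, and the other 9 libraries sit between -42.2 and -11.8.

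After 0.5 h in the cold, edgeR called few genes as different from the control. PH01001566G0280 rose from 1.86 ± 0.425 CPM in the controls (SD, n = 3) to 23.6 ± 10 CPM (SD, n = 3), a log2 fold change of 3.67 (SE 0.33, edgeR adjusted p = 0.0037). PH01221966G0010 fell from 3.01 ± 0.532 CPM to 0.128 ± 0.0375 CPM (SD, n = 3 each), a log2 fold change of -4.53 (SE 0.35, edgeR adjusted p = 0.0022). This gene was singled out after its values were seen, because it was the only gene called lower at this time, and it was counted thinly, with 76 to 121 counts in the control libraries and 3 to 5 in the 0.5 h libraries. The other two called genes rose, with log2 fold changes of 2.28 (SE 0.19, edgeR adjusted p = 0.0022) and 1.11 (SE 0.13, edgeR adjusted p = 0.04). In all, edgeR's quasi-likelihood test called 4 of 39640 genes, 3 higher and 1 lower, while 1838 genes (4.64%) had an unadjusted p under 0.05. DESeq2 called 216 genes on the same counts, 183 higher and 33 lower, among them all 4. Of the 183, edgeR called 133 higher and 0 lower at 24 h. Of the 33, it called 0 higher and 8 lower at 24 h. Both comparisons share the control libraries, so these overlaps are not independent. The edgeR count was 9 in a fit of only the groups compared, 4 higher and 5 lower, 8 with no filter on low counts, 10 with a stricter filter, 24 without 0.5 h replicate 2 and 8 without 0.5 h replicate 3.

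After 1 h, PH01001566G0280 was again higher than in the controls, at 14.7 ± 4.26 CPM (SD, n = 3) against 1.86 ± 0.425 CPM (SD, n = 3). Its log2 fold change was 2.99 (SE 0.32, edgeR adjusted p = 0.037). The only other gene called at 1 h rose by 1.71 on the log2 scale (SE 0.19, edgeR adjusted p = 0.037). Both had been called higher at 0.5 h. PH01221966G0010 was back at 3.4 ± 0.798 CPM (SD, n = 3), with a log2 fold change against the control of 0.18 (SE 0.28, edgeR adjusted p = 0.94). No gene was called lower by edgeR, although 1303 genes were lower and 1424 higher at an unadjusted p under 0.05, DESeq2 called 54 lower and 119 higher, and edgeR called 2 lower and 6 higher in a fit of only the groups compared. The calls at 1 h and their direction changed with single libraries: edgeR called 0 genes without control replicate 1, 2 or 3, 1 higher and 2 lower without 1 h replicate 1, 0 higher and 3 lower without 1 h replicate 2, and 8 higher and 5 lower without 1 h replicate 3. The log2 fold change of PH01001566G0280 was 2.89, 2.92 and 3.19 without control replicates 1, 2 and 3 (edgeR adjusted p = 0.16, 0.2 and 0.17) and 3.03 and 2.75 without 1 h replicates 1 and 2 (edgeR adjusted p = 0.063 for both), so its size was kept while its call was lost.

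**Figure D2:**
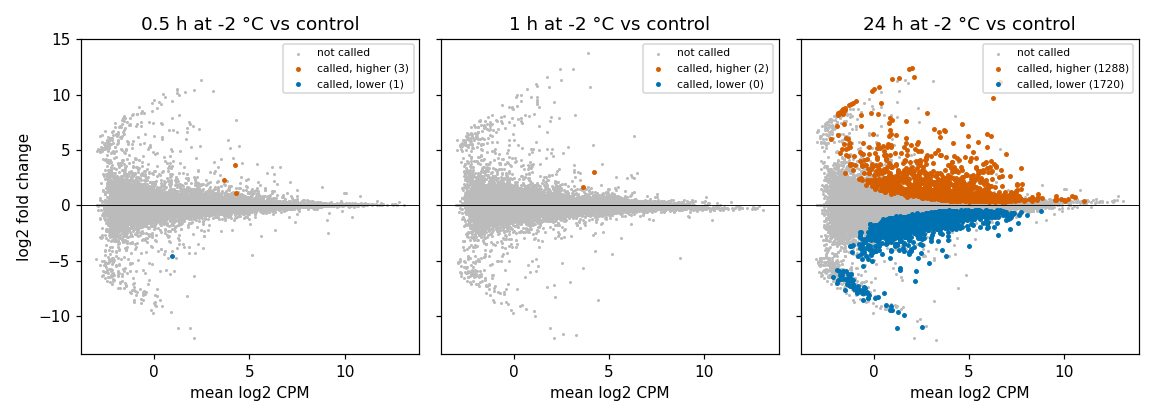
Each point is 1 of 39640 genes, with its mean log2 CPM over the 11 libraries on the horizontal axis and its edgeR log2 fold change against the control on the vertical axis, for 0.5 h, 1 h and 24 h at -2 °C. Genes called at an adjusted p under 0.05 are coloured by direction: 3 higher and 1 lower at 0.5 h, 2 higher at 1 h, and 1288 higher and 1720 lower at 24 h.

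After 24 h, 1288 genes were higher and 1720 lower than in the controls. PH01001480G0410 had the largest rise among the genes open to naming, from 0.499 ± 0.673 CPM in the controls (SD, n = 3) to 418 ± 44.7 CPM (SD, n = 2), a log2 fold change of 9.68 (SE 0.68, edgeR adjusted p = 2.1e-05). Its control level rested on 3 to 43 counts per library, against 11598 and 12026 counts at 24 h. Without control replicate 1, which held the 43 counts, the log2 fold change was 11.8 (edgeR adjusted p = 1.9e-05). Over its alternatives the adjusted p ran from 3.8e-20 with DESeq2 to 0.0012 with edgeR. PH01000320G0510 had the largest fall, from 18.9 ± 4.02 CPM (SD, n = 3) to 0.804 ± 0.184 CPM (SD, n = 2), a log2 fold change of -4.54 (SE 0.27, edgeR adjusted p = 7.9e-06). PH01001566G0280 reached 41.6 ± 1.68 CPM (SD, n = 2), a log2 fold change of 4.49 (SE 0.35, edgeR adjusted p = 3.9e-05). PH01221966G0010 was low again, at 0.175 ± 0.0357 CPM (SD, n = 2), with a log2 fold change of -4.07 (SE 0.41, edgeR adjusted p = 2e-04).

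**Figure D3:**
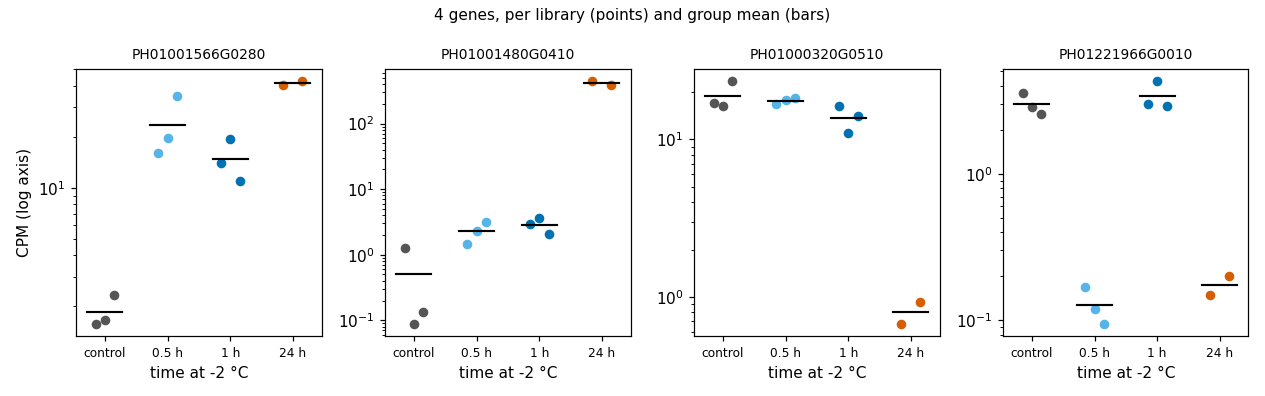
CPM of 4 genes in each library (points) and the group mean (bars) in the controls and after 0.5 h, 1 h and 24 h at -2 °C, each on its own logarithmic axis. PH01001480G0410 reaches a mean of 418 CPM at 24 h from 0.499 CPM in the controls, and PH01221966G0010 lies near 3 CPM in the controls and at 1 h, and below 0.3 CPM at 0.5 h and 24 h.

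The genes called at 24 h made up 7.59% of those tested. Among them, 726 rose and 1091 fell at least 2-fold, 398 rose and 362 fell at least 4-fold, and 133 rose and 98 fell at least 16-fold. The risen genes had a median of 9.81 CPM in the controls and 25.4 CPM at 24 h, and a median log2 fold change of 1.18. The fallen genes had medians of 8.79 CPM and 3.87 CPM, and a median log2 fold change of -1.21. The risen genes together took 4.28% ± 0.204 of the counts in the controls (SD, n = 3) and 7.66% ± 0.19 at 24 h (SD, n = 2), and the fallen genes took 3.05% ± 0.168 and 1.42% ± 0.00399. Because both sets were chosen on these libraries, their shares describe the calls and do not test them. A group of 43 genes lay below 1 CPM in all controls and at 5 CPM or more in both 24 h libraries, of which 42 were called higher, and 11 genes did the reverse, of which 10 were called lower.

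At 24 h, 6.0% of the genes listed as newGene and 8.31% of the genes with a PH01 identifier were called, and the gap varied with abundance. Up to a mean log2 CPM of 1, 2.92% of newGene entries and 4.83% of the others were called (two-sided Fisher's exact test over genes, which are not independent replicates, p = 6.96e-08), and from 1 to 3 the shares were 7.83% and 10.4% (Fisher's exact p = 6.14e-05). From 3 to 5 the shares were 9.42% and 9.15% (Fisher's exact p = 0.691), and above 5 they were 9.97% and 8.35% (Fisher's exact p = 0.0929).

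The split between risen and fallen genes at 24 h depended on the scaling. With library size alone in place of TMM factors, 858 genes were higher and 2963 lower, a share of 22.5% higher against 42.8% with TMM. The median log2 fold change of all genes was then -0.176 in place of -0.012. Upper-quartile factors gave 1097 higher and 1968 lower (35.8% higher), and RLE factors 1343 and 1679 (44.4% higher). The TMM factors of the 24 h libraries were 0.892 and 0.923, and those of the other libraries 0.982 to 1.064. The count of 3008 genes was 4895 with DESeq2, 1948 in a fit of only the groups compared, 1281 without 24 h replicate 2, 1357 without 24 h replicate 1, 1873 without control replicate 2 and 1978 without control replicate 1. Without a 24 h replicate, the remaining 24 h library is assumed to vary like the other groups.

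Between consecutive times, edgeR called 1 gene from 0.5 h to 1 h and 3851 genes from 1 h to 24 h. PH01221966G0010 was the only gene called between 0.5 h and 1 h, with a log2 fold change of 4.70 (SE 0.35, edgeR adjusted p = 0.0019). No gene was called lower at 1 h than at 0.5 h by edgeR, while 1470 genes were lower and 1290 higher at an unadjusted p under 0.05, DESeq2 called 66 lower and 70 higher, and edgeR called 3 lower and 1 higher in a fit of only the groups compared. The count of 1 became 2 without 0.5 h replicate 1 (2 higher) or 2 (1 higher, 1 lower), and 6, 4 and 11 without 1 h replicates 1, 2 and 3, of which 1, 3 and 6 were lower. From 1 h to 24 h, 1844 genes rose and 2007 fell. PH01001480G0410 rose by 7.18 on the log2 scale (SE 0.59, edgeR adjusted p = 8.1e-05), PH01001566G0280 rose by 1.5 (SE 0.31, edgeR adjusted p = 0.015), and PH01000320G0510 fell by 4.08 (SE 0.27, edgeR adjusted p = 2.3e-05). The control cancels in this contrast, so it also tests whether the fold change against the control differs between 24 h and 1 h. With library size alone the split was 963 higher and 4245 lower, against 1844 and 2007, and the median log2 fold change was -0.251 against -0.033. Upper-quartile factors gave 1554 higher and 2273 lower, and RLE factors 1916 and 1962. The count of 3851 was 5929 with DESeq2, 1711 in a fit of only the groups compared (962 higher, 749 lower), 1260 and 1347 without 24 h replicates 1 and 2, and 2498 and 2522 without 1 h replicates 2 and 3.

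Most of the genes called at 24 h belonged to the late class, meaning that they differed from the control at 24 h, differed in the same direction from 1 h, and were called at neither earlier time. This class held 2277 genes, 928 higher and 1349 lower. The last condition removed few genes, since 2281 were called in the same direction in both 24 h contrasts. A gene not called early may still have changed by then. PH01001480G0410 is in this class, although it was 5.63-fold higher at 1 h than in the controls (edgeR adjusted p = 0.56). Another 727 genes were called at 24 h against the control and not against 1 h. A sustained change, called in the same direction at 1 h and 24 h, was found in 2 genes, one of them PH01001566G0280. No gene was called by edgeR at 0.5 h or 1 h and in the opposite direction from 1 h to 24 h, and no gene in opposite directions at an early time and at 24 h. At unadjusted p-values under 0.05 these last 2 classes held 1060 and 256 genes, and with DESeq2 they held 57 and 4. The first of them, early and returning, leaves out a return between 0.5 h and 1 h, as seen in PH01221966G0010. The 1 h libraries enter 1 h against control and 24 h against 1 h with opposite signs. Noise in the 1 h libraries alone can therefore put a gene in that class, so its counts do not show that genes came back. In a single test of any difference from the control, edgeR called 1869 genes and DESeq2 4955, and the late class held 3481 genes with DESeq2. The edgeR count was 522 and 572 without 24 h replicates 2 and 1, and the late class then held 924 and 957 genes. The sustained class held 0 genes without control replicate 1, 2 or 3, without 0.5 h replicate 1 or without either 24 h replicate, 1 without 1 h replicate 1 or 2, and 5 without 0.5 h replicate 3 or 1 h replicate 3. The early and returning class held 1 gene without control replicate 1 or 24 h replicate 1, and 2, 3 and 9 genes without 1 h replicates 1, 2 and 3.

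All 4 genes called at 0.5 h were called in the same direction at 24 h, and both genes called at 1 h were called higher at 24 h. Independent lists of these sizes would share 0.14 and 0.065 genes. The comparisons share the 3 control libraries, so fold changes correlate with no effect at all. Over the 18438 genes with a mean log2 CPM of at least 3, the covariance of log2 fold changes between 0.5 h and 24 h was 0.0729, against a mean of 0.0304 and a highest value of 0.0354 in 20 simulations of unchanged groups against the same number of controls. Between 1 h and 24 h it was 0.0388, against a mean of 0.0308 and a highest value of 0.0421. Between 0.5 h and 1 h it was 0.0431, against 0.0303 and 0.0416. The corresponding correlations were 0.488, 0.208 and 0.491 observed, and 0.44, 0.446 and 0.503 on average in the simulations. The simulated groups shared 0 called genes, which unchanged groups give nearly by construction and which adds no weight to the shared calls. The 3 controls cannot be split so that each part keeps 2 libraries, so part of the excess may come from the shared controls. The simulated counts were drawn from fitted dispersions and may lack the more extreme spread of some real genes. Counts drawn this way in the test of the scripts at 0.5 h had 6.24 prior degrees of freedom, against 3.86 in the real fit. The highest simulated values may therefore be too low.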

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

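The tests of a length trend, library size and a few abundant genes, those of counting noise, the cold, alleles and reads moving to 1 gene over 8-fold lower elsewhere as sources of single-library losses, the permutation of those losses over libraries, and the directional test of the early shift at 0.5 h were chosen only after the results or a first look at them were seen; the bound for thinned libraries was set before that fit was run. Each of the following differences between times was singled out because the difference itself passed edgeR's test at an adjusted p under 0.05. No group has 4 libraries, so no library was tested as an outlier within its group.

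The fold change against the control differed between 1 h and 24 h for 3851 genes, and between 0.5 h and 1 h for 1 gene. Since the control cancels, these are the contrasts between times given above. With 1 control group for all times, a harvest time or batch that follows the groups cannot be told apart from the cold. Among the named genes, the log2 difference between 24 h and 1 h was 1.5 for PH01001566G0280, 7.18 for PH01001480G0410 and -4.08 for PH01000320G0510. PH01221966G0010 differed by 4.70 between 1 h and 0.5 h and by -4.25 between 24 h and 1 h. It was high in each library of the control and 1 h groups (76 to 150 counts) and low in each library of the 0.5 h and 24 h groups (3 to 6 counts).

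The first pattern is the response at 24 h. Removing a smooth gene-length trend from each library left 98.6% of the 3008 called genes called in the same direction, which argues against a length trend as its source. Library size is argued against by the totals: 29953291 and 32510246 counts at 24 h, within the 29304206 to 34543663 of the other libraries. Thinning every library to the smallest total removed few counts and was a weak test. It left 95.1% of these genes called in the same direction. A few dominant genes are argued against too, since the 10 most abundant took at most 7.33% of the counts of a 24 h library. The split of the calls into higher and lower still depends on the scaling. A day, batch or chamber difference that follows the groups is not in the labels and cannot be told apart from the cold, and no biological explanation beyond the cold itself was tested.

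The real grouping was compared with the other ways to split the same libraries, 10 splits in each comparison, too few for a share under 0.05. Every other split mixes the groups compared, so a real difference between them adds to the spread within groups and lowers the calls. Low counts in the other splits are therefore partly built in. For 24 h against control the real split called 3008 genes and the highest other split 2, with 1 split as large as the real one (the real one itself). For 24 h against 1 h the values were 3851 and 8, with 1 split. For 0.5 h against control they were 4 and 3, with 1 split. For 1 h against control they were 2 and 2, with 4 splits, and for 1 h against 0.5 h they were 1 and 2, with 7 splits.

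The second pattern is 46 genes that were over 8-fold lower in a single library than in any other, with a mean log2 CPM of at least 3 in the other 10 and 0 to 290 counts in the library of the loss. The lowest count expected in the library of the loss was 229 and the median 571, so shortfalls over 8-fold are beyond counting noise. The limits on level and gap chose such genes in advance, so these values describe the choice and are no separate test. For 91.3% of them another gene gained 0.5 to 2 times the lost amount in that library alone, which met the bound set beforehand for misassigned reads, but the same search in libraries without the loss succeeded for 89.8%, and a narrower search for gained genes gave 67.4% against 55.9%, so neither search decides. The losses numbered 6 in the controls, 9 at 0.5 h, 14 at 1 h and 17 at 24 h, a group of 2 libraries. The mean was 8.5 per 24 h library and 3.22 per library of the other groups. A binomial test of the cold as their source gave an exact one-sided p of 0.018, but it treats genes as independent while losses ranged from 1 to 9 per library. An exact permutation of the 11 libraries gave p = 0.12. Both pool the cold times, so neither tests the higher mean at 24 h, and the cold stays open. Seedlings that carry different alleles may also give such losses: 10.7% of the other libraries lay at 0.35 to 0.65 of the gene's usual level, against 5.66% for genes of like abundance (permutation p = 0.003), while 17.0% lay at 0.65 to 0.80, against 15.0%; the first excess goes with alleles, but the share at 0.35 to 0.65 was not above that at 0.65 to 0.80, which a separate middle level would give, and whether these genes vary more in general was not tested, so this too stays open.

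The third pattern is an early shift of the genes that change later. Genes called from 1 h to 24 h, in a fit of those libraries alone, were measured from control to 0.5 h in libraries that did not enter their choice: 693 of 878 risen genes (78.9%) were higher at 0.5 h, with a median log2 shift of 0.15, and 492 of 743 fallen genes (66.2%) were lower, with a median of -0.07, while 48.7% of the other genes were higher. The directional fry test of limma, which measures the shift against the spread between libraries, gave an adjusted p = 0.075 for the risen genes, 0.042 before adjustment over 4 sets, and an adjusted p = 0.21 for the fallen genes. For the genes that rose or fell at least 4-fold, 2 sets beyond those the test was written for, it gave an adjusted p = 0.075 each, although 208 of 253 risen genes (82.2%) were higher, with a median of 0.67, and 115 of 187 fallen genes (61.5%) lower, with a median of -0.10; 4 of the 10 splits of the 6 libraries gave a gap between the full sets at least as large (0.223 in the real split, 0.305 in the highest other). The mirror test, of genes called from 0.5 h to 24 h and measured from control to 1 h, gave an adjusted p = 0.092 for the risen genes, 0.069 before adjustment, and an adjusted p = 0.32 for the fallen genes. There both 4-fold sets passed, with an adjusted p = 0.033 each: 130 of 168 risen genes (77.4%) were higher at 1 h, with a median log2 shift of 0.48, and 115 of 171 fallen genes (67.3%) were lower, with a median of -0.15, and 2 of the 10 splits gave a gap between the full sets at least as large (0.17 in the real split, 0.253 in the highest other). Gene length and abundance are argued against, since 100% of the gap at 0.5 h was kept relative to genes of like length and abundance. An early start of the 24 h response may underlie the shift, as the 4-fold sets at 1 h would have it, but the full sets, for which the bound had been set, did not both pass at either time, so it stays open.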

How the results depend on the processing

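The robust spread, the length trend removal and the fit without single-library genes were chosen only after the results were seen. Scaling by RLE factors or the upper quartile left each count of calls within 1.5 times its value in the report. So did the length trend removal and the fit without single-library genes. The splits into higher and lower given there moved with library size alone and, less so, with the upper quartile. At equal totals of 29304206 counts, also chosen later, 2973 genes were called at 24 h. With DESeq2 in place of edgeR the counts were 216 at 0.5 h, 173 at 1 h, 4895 at 24 h, 136 for 1 h against 0.5 h, 5929 for 24 h against 1 h and 4955 for any cold time (166 or 935 genes had no adjusted p). DESeq2 put 57 genes in the early and returning class, 96 in the sustained, 3481 in the late and 4 in the opposite class, and found 80 genes shared by 0.5 h and 1 h, 159 by 0.5 h and 24 h and 96 by 1 h and 24 h. It shared 2995 of edgeR's 3008 genes at 24 h. Fitting only the groups compared gave 9 genes at 0.5 h (4 higher, 5 lower), 8 at 1 h (6 and 2), 1948 at 24 h (934 and 1014), 4 for 1 h against 0.5 h (1 and 3) and 1711 for 24 h against 1 h (962 and 749). At 0.5 h, 8 genes were called with no filter, 10 with the stricter filter and 10 with the robust spread, and the same numbers were shared with 24 h. The cause of these differences was not tested.

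An adjusted p under 0.01 left 0 genes at 1 h, 1100 at 24 h, 1114 from 1 h to 24 h, 613 for any cold time, 0 sustained, 782 late, 0 shared by 0.5 h and 1 h and 0 shared by 1 h and 24 h. A 2-fold limit left 1817 genes at 24 h, 1872 from 1 h to 24 h and 1338 late. Over genes with a mean log2 CPM of at least 3, fold changes correlated at 0.488 (0.5 h and 24 h) and 0.208 (1 h and 24 h), against 0.408 and 0.351 over all genes. The first component held 20.9% of the variance with a prior count of 0.5 and 16.3% over the 500 most variable genes.

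The replicate numbers showed no sign of pairing the samples. Deviations of same-numbered libraries from their group means correlated at -0.179 to 0.122 over 15 pairs, 2 of them over 0.1. Those of different-numbered libraries correlated at -0.235 to 0.264 over 30 pairs, 3 of them over 0.1. Only 1 of 11 libraries correlated best with its own number. With the number as a block, 4 genes were called at 0.5 h, 0 at 1 h, 2075 at 24 h, 1 for 1 h against 0.5 h, 2712 for 24 h against 1 h and 934 for any cold time, with 0 sustained, 0 shared by 0.5 h and 1 h and 0 shared by 1 h and 24 h. The 1 h log2 fold change of PH01001566G0280 was then 3.03 (edgeR adjusted p = 0.11). Over its alternatives the adjusted p ran from 2.3e-17 with DESeq2 to 0.2 with edgeR, and the lowest edgeR value was 0.015.

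Leaving out 1 library at a time gave 3 to 24 genes at 0.5 h, 0 to 13 at 1 h, 1281 to 2789 at 24 h, 1 to 11 for 1 h against 0.5 h, 1260 to 3016 for 24 h against 1 h and 522 to 1773 for any cold time. The classes held 0 to 9 (early and returning), 0 to 5 (sustained), 924 to 2232 (late) and 0 (opposite). Shared genes numbered 0 to 4 (0.5 h and 1 h), 3 to 22 (0.5 h and 24 h) and 0 to 5 (1 h and 24 h), with correlations of 0.433 to 0.651, 0.34 to 0.5 and 0.283 to 0.454, and the first component held 19.8% to 25%. For each comparison of 2 groups, the range of calls covers only the libraries of those groups. For the joint test, the classes, the shared genes, the correlations and the first component, it covers all 11 libraries. The lowest 24 h counts came without 24 h replicate 2 (1281) and 24 h replicate 1 (1357), which leaves 1 library in that group. PH01001480G0410 and PH01000320G0510 at 24 h against control, and PH01221966G0010 at 0.5 h against control, kept their direction and call under each alternative run; their other comparisons were not recomputed. The gene lists and the fit without 24 h replicate 3 were not run. Low counts limit what a fold change shows: the controls held 43, 3 and 4 counts of PH01001480G0410, which was 4.54-fold higher at 0.5 h (edgeR adjusted p = 0.64).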

Other observations

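Along the direction that separates the 24 h libraries, the 0.5 h libraries lay nearer to 24 h than the 1 h libraries did, a comparison chosen after the data were seen. On the first principal component the 0.5 h libraries lay at -17.7, -20.8 and -11.8 and the 1 h libraries at -29.3, -37.0 and -31.0, with no overlap, which chance gives in 10% of comparisons of 3 libraries with 3. The controls lay at -41.6, -42.2 and -26.7. The genes that rose at 24 h took 4.89% ± 0.0923 of the counts at 0.5 h and 4.50% ± 0.052 at 1 h (SD, n = 3 each), against 4.28% ± 0.204 in the controls, and the genes that fell took 2.76% ± 0.0475 and 2.97% ± 0.14, against 3.05% ± 0.168. These sets were chosen on the control and 24 h libraries, so the distances from the controls are not independent of the choice, and the difference between 0.5 h and 1 h was not tested.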
